A study of Homo sapiens with 32 samples.

How the data were processed

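Skin biopsies of 16 participants with diffuse cutaneous systemic sclerosis, 12 given an IL-1 inhibitor and 4 placebo for 42 days, were profiled before and after treatment on 32 one-colour Affymetrix arrays. RNA was purified on RNeasy columns and labelled with biotin, per the labels' protocols. The array model is not given in the sources used here. The deposited values are log2 expression levels made by the authors with the R package affy and robust multi-array averaging (RMA), per the submitters' processing notes, which name no versions. RMA subtracts background, makes the arrays' distributions alike and summarises the probes of a gene, so a shift shared by all genes of an array would not be seen. The table held 12264 entries with values from 1.98 to 14.33. Array medians between 6.642 and 6.719 were close to each other, as that normalization makes them. Arrays give no read depth, and their number limits the precision.

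Of the 12264 entries, 11727 had 1 gene symbol in the annotation given, none had several and 537 had none and are unnamed here. There was 1 entry per gene, so no choice among probe sets was needed. 23 entries of genes on the Y chromosome or of XIST were left out, which left 11704 genes. Those on the Y chromosome served only to look for mixed-up biopsies, and in 0 pairs did both biopsies disagree in Y-linked expression. That check cannot see a mix-up between participants alike in Y-linked expression, or one of visits within a pair. A gene of the naming rule is not reported here.

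The arm, the visit and the participant came from the labels, and arrays of one participant were paired because the titles give both biopsies the same participant number. Deviations from the group means correlated within each pair (lowest 0.319, median 0.495, highest 0.814). Among second biopsies of the same arm, 15 of 16 first biopsies were closest to that of the same participant. The median share of a gene's variance that lay between participants was 43.3%. Gene changes were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 32 arrays, with the participant as a fixed block and a post-treatment term per arm. The difference between arms was the difference of these terms. The arms before treatment were compared on the 16 first biopsies. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05, and errors of gene changes are standard errors from the same fits.

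The 39 gene lists, of pathways and of cell types of skin, were fixed before the data were examined, and each had at least 4 measured genes. The list change of a participant was the mean change over its genes. It was tested with an exact two-sided sign-flip permutation test in the drug arm (4096 sign patterns) and with an exact two-sided permutation of the arm labels for differences between arms (1820 splits), adjusted over the 39 lists. Intervals of 95% come from inverting these tests. Where a gene is said to pass over a list alone, its limma p was adjusted over that list's genes, with no allowance for the 39 lists. Among lists with no change, a share of about 0.05 would hold such a gene by chance in each comparison. Correlations used 100000 permutations. limma's camera was run with its preset and with an estimated correlation between genes. These steps ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

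The genes named in the text followed a rule fixed in advance. Where fewer than 10 genes passed, it took the 10 genes with the smallest p in the drug arm and in the difference, and 5 each for the placebo arm and the comparison before treatment. It added fixed genes of the IL-1 pathway, fibrosis and skin biomarkers, and up to 4 members with the smallest p from each of the 4 lists with the smallest p. PMEL, TYRP1, RGS1 and TNFSF14 fall outside this rule and were named after their values were seen.

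The fit was tested on simulated data with 200 of 11704 genes changed. Noise was drawn independently for each gene, and a change was the same in every participant of an arm. In the real data genes vary together and changes differ between participants, so the shares below may overstate the power there. In the drug arm the fit recovered 50.5% of simulated changes of 0.25, 92.4% of changes of 0.5 and 98.7% of changes of 1 (log2). In the placebo arm these shares were 1.7%, 66.9% and 94%, and for the difference between arms 0%, 51% and 92.7%. Alternatives covered the participant block, the arrays in the fit, the variance model, array weights, a filter on dim genes, another normalization, camera, the list summary, leaving out pairs, and the levels of skin appendage lists as covariates.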

Results

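Skin gene expression was measured in participants with diffuse cutaneous systemic sclerosis, an autoimmune disease in which the skin thickens through deposition of extracellular matrix. Participants were randomised to a drug that inhibits interleukin-1 (IL-1), a cytokine of innate inflammation, or to placebo for 42 days, and a skin biopsy was taken before and after treatment. The data comprised 32 one-colour Affymetrix arrays from 16 participants, with 12 pairs of biopsies in the drug arm and 4 in the placebo arm. Values were log2 expression levels from robust multi-array averaging, and array medians lay between 6.642 and 6.719. The number of arrays, 4 placebo pairs above all, limits the precision of each comparison. Changes are given as the level after treatment minus the level before it, on the log2 scale.

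The first comparison asked which genes changed in skin under the IL-1 inhibitor. IL-1 pathway genes showed mean changes near 0 in the 12 drug pairs. The list of 16 IL-1 ligands, receptors and inflammasome genes had a mean change of -0.005 ± 0.140 (SD, n = 12, 95% interval -0.0953 to 0.0857, exact sign-flip p = 0.917). The 29 genes that IL-1 induces in fibroblasts and keratinocytes had a mean change of -0.01 ± 0.16 (SD, n = 12, 95% interval -0.118 to 0.0829, exact sign-flip p = 0.817), with 6 pairs up and 6 down. IL1B, which encodes IL-1 beta, was at 5.37 ± 0.39 before and 5.25 ± 0.35 after the drug (SD, n = 12), a change of -0.13 ± 0.08 (SE) with lower values in 9 of 12 pairs. IL1A, encoding IL-1 alpha, had a change of -0.11 ± 0.17 (SE) at a mean level of 3.90, and IL1RN, the natural receptor antagonist, one of 0.06 ± 0.08 (SE). In a single drug pair IL1A rose from 3.64 to 5.56, and its mean change rests in part on that pair. The receptor genes IL1R1, IL1R2 and IL1RAP had changes of -0.04 ± 0.04, -0.04 ± 0.12 and 0.08 ± 0.06 (SE).

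Cytokines and chemokines downstream of IL-1 did not pass the test in the drug arm. IL6, a cytokine that IL-1 induces in fibroblasts, had a change of 0.20 ± 0.13 (SE), up in 9 of 12 pairs. CXCL8, a neutrophil chemoattractant, had a change of -0.03 ± 0.07, and CCL2, a monocyte chemoattractant, one of -0.14 ± 0.15. The mean level of CXCL8, 3.43 against a median gene level of 6.70, was low, so a change near 0 says little about it. CCL18, a chemokine of alternatively activated macrophages, had a change of 0.13 ± 0.34 and ranged widely between participants (SD before treatment 1.19, n = 12). The list of 18 genes of the IL-6, JAK and STAT3 response had a mean change of -0.04 ± 0.12 (SD, n = 12), and the 15 NF-kappaB pathway genes one of -0.008 ± 0.166. The type I interferon list had a mean change of -0.04 ± 0.72 (SD, n = 12), and 11 acute phase and IL-17 type keratinocyte genes one of -0.30 ± 0.79, with 10 of the 11 members below 0. Under placebo the acute phase list fell further, by -0.68 ± 0.76 (SD, n = 4), a difference between arms of 0.37 (exact permutation p = 0.423). In the drug arm the smallest adjusted p of these lists by exact sign-flip test was 0.795. In the 10 drug pairs whose first array carried no second code in its title, mean changes were -0.13 for the type I interferon list, 0.01 for IL1A, 0.13 for IL1RN, 0.09 for IL6, -0.02 for CCL2 and -0.07 for CCL18. A pair among these 10 moved from 3.64 to 5.56 in IL1A. Another moved from 9.16 to 7.88 in CCL2 and from 10.4 to 7.64 in CCL18. The signs of these 3 means rest on those single pairs.

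**Figure D1:**
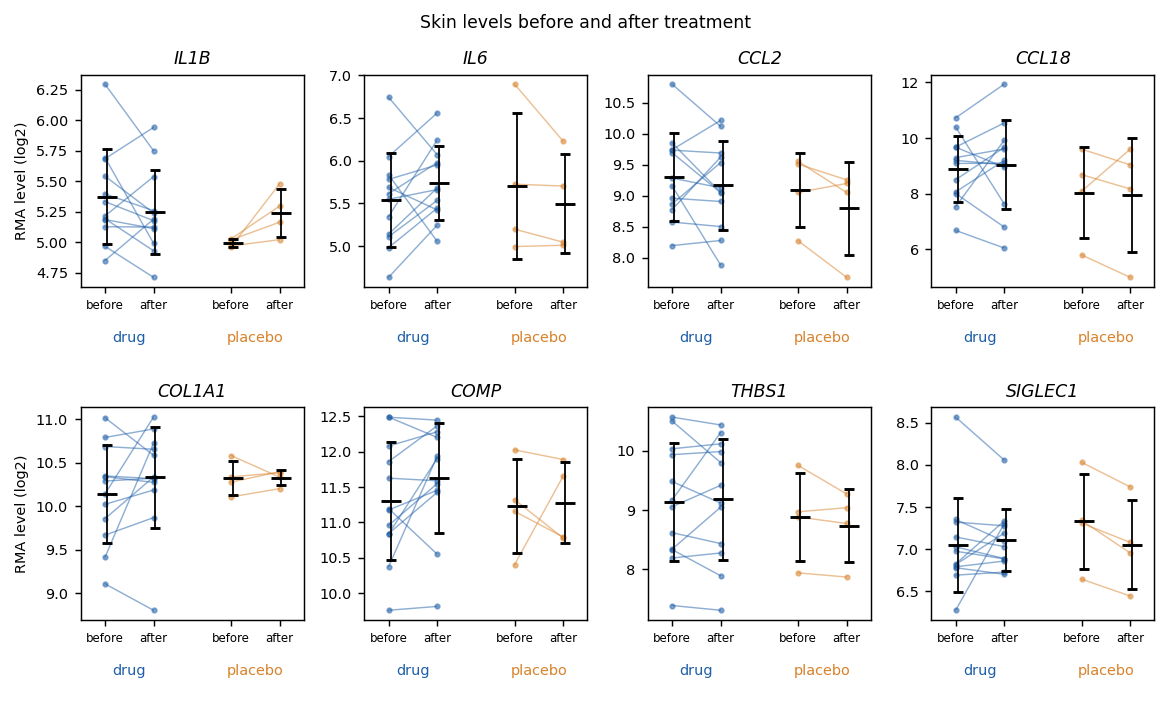
Robust multi-array average levels (log2, vertical axes) of 8 genes before and after treatment, with a line per participant for the drug arm (12 pairs) and the placebo arm (4 pairs), and black bars for the mean and SD. The lines of all 8 genes run both ways in the drug arm. IL1B was lower and IL6 higher in 9 of 12 drug pairs. In all 4 placebo pairs IL1B was higher and SIGLEC1 lower after treatment. Before treatment IL1B was at 5.37 in the drug arm and 4.99 in the placebo arm.

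Genes of fibrosis had mean changes above 0 in the drug arm that did not pass the test. Of the 22 genes in the list of other extracellular matrix, 21 had a mean change above 0 and none passed, and the list mean was 0.12 ± 0.31 (SD, n = 12, exact sign-flip p = 0.224, adjusted p = 0.795). This mean was 0.02 in the 10 drug pairs with no second code. The 16 fibrillar collagen and crosslinking genes had a list mean of 0.11 ± 0.26 (SD, n = 12) and one of 0.02 in those 10 pairs. COL1A1, a chain of type I collagen, had a change of 0.19 ± 0.12 (SE) and a mean of 0.05 in those 10 pairs, and POSTN, the matricellular protein periostin, one of 0.11 ± 0.05 (SE, limma p = 0.0404, adjusted p = 0.818) and a mean of 0.08 in those 10. The 6 skin biomarker genes of systemic sclerosis had a list mean of 0.06 ± 0.32 (SD, n = 12) and one of -0.04 in those 10 pairs. Among them COMP, a cartilage matrix protein, had a change of 0.32 ± 0.17 (SE) and a mean of 0.12 in those 10 pairs, THBS1, the TGF-beta activator thrombospondin 1, one of 0.04 ± 0.12 and a mean of -0.05 in those 10, and IFI44, an interferon-inducible gene, one of -0.08 ± 0.15 and a mean of -0.16 in those 10. Both means of IFI44 rest largely on a single pair among those 10, which fell from 10.5 to 9.23. The macrophage genes SIGLEC1 and MS4A4A had changes of 0.07 ± 0.10 and 0.03 ± 0.10 (SE), and means of -0.06 and -0.05 in those 10 pairs.

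Lipid synthesis genes had the smallest p of the 39 lists in the drug arm. The 12 genes of lipid and sterol synthesis had a mean change of -0.29 ± 0.39 (SD, n = 12, 95% interval -0.540 to -0.0482), below 0 in 9 of 12 pairs, with an exact sign-flip p of 0.0190 and an adjusted p of 0.743. All 12 members had a mean change below 0 and none passed over all genes tested. When adjusted over the list alone, without allowance for the 39 lists, 2 passed. These were SCD, a fatty acid desaturase, with -0.56 ± 0.17 (SE, below 0 in 10 of 12 pairs), and ELOVL6, a fatty acid elongase, with -0.28 ± 0.09. With each of the 16 pairs left out in turn, each of these 2 genes still passed over the list in 12 of 16 fits (highest list-alone adjusted p 0.0669). INSIG1, a brake on sterol synthesis, had a change of -0.60 ± 0.23, and SC5D, a late enzyme of cholesterol synthesis, one of -0.25 ± 0.12. Drug pairs that fell from 10.7 to 8.8, 9.2 to 7.5 and 9.6 to 7.4 in INSIG1 fell from 7.24 to 6.42, 6.86 to 6.00 and 7.34 to 6.28 in SC5D. Both means rest largely on these pairs. Over 16 participants the change of the list without SCD correlated with that of 6 sebocyte genes outside it (r = 0.964 and rho = 0.950, permutation p = 1e-05 for each). Sebaceous gland genes had a mean change of -0.46 ± 0.83 (SD, n = 12, exact sign-flip p = 0.0796) and hair follicle genes one of -0.74 ± 1.41 (SD, n = 12, exact sign-flip p = 0.0957). Under placebo the lipid, sebaceous and hair follicle lists had mean changes of 0.07 ± 0.44, 0.23 ± 0.98 and -0.43 ± 2.13 (SD, n = 4). The differences between arms were -0.36, -0.70 and -0.31 (exact permutation p = 0.141, 0.187 and 0.738). In the drug arm FAR2 and FADS2, enzymes of sebaceous lipid synthesis, had changes of -0.78 ± 0.42 and -0.48 ± 0.34 (SE), and MC5R, a melanocortin receptor of sebocytes, one of -0.04 ± 0.12. A single drug pair fell from 10.1 to 5.72 in FAR2 and from 9.57 to 6.26 in FADS2. These changes and the sebaceous list mean rest in part on that pair. The hair keratins KRT34 and KRT31 had changes of -1.58 ± 0.72 and -0.93 ± 0.47, and the hair follicle transcription factors SOX9 and LHX2 had changes of -0.22 ± 0.10 and -0.41 ± 0.24.

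Cell type markers in the drug arm gave a lymphatic list mean of 0.15 ± 0.23 (SD, n = 12, exact sign-flip p = 0.0518), in which CCL21, a lymphatic chemokine, and TFF3, a trefoil factor, passed when adjusted over the list alone and not over all genes. CCL21 had a change of 0.41 ± 0.14 (SE) and TFF3 one of 0.31 ± 0.11, and with each pair left out in turn they still passed over the list in 10 and 9 of 16 fits. Of the 6 lymphatic genes 4 had a mean change above 0 and 2 below, and the receptors FLT4 and LYVE1 had changes of 0.07 ± 0.09 and 0.11 ± 0.20, the latter with a mean of -0.04 in the 10 pairs with no second code. All 16 macrophage genes had a mean change above 0, with a list mean of 0.08 ± 0.30 (SD, n = 12, exact sign-flip p = 0.397) and one of -0.02 in the 10 pairs with no second code. Neutrophil, T and NK cell, B and plasma cell and mast cell genes had mean changes of -0.06 ± 0.30, 0.01 ± 0.34, 0.01 ± 0.49 and 0.07 ± 0.15 (SD, n = 12). None of these lists passed (exact sign-flip p = 0.498, 0.893, 0.924 and 0.155). Fibroblast genes had a mean change of 0.09 ± 0.29 and one of 0.01 in the same 10 pairs, and basal and differentiated keratinocyte genes means of -0.01 ± 0.09 and -0.06 ± 0.26.

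No gene passed an adjusted p of 0.05 in the drug arm by limma. At an unadjusted p under 0.05 there were 694 genes, 397 higher and 297 lower, against 585.2 that 11704 tests give by chance, and the smallest adjusted p was 0.818. The smallest p belonged to RHOBTB2, with a change of 0.24 ± 0.05 (SE) that was above 0 in 12 of 12 pairs. CRIPT had a change of -0.27 ± 0.06, below 0 in 12 of 12 pairs, and NEB, the sarcomere protein nebulin, one of -0.47 ± 0.11. NEB passed when adjusted over the skeletal muscle list alone, but it had been picked for its small p, so that pass adds no support. Its mean level was 4.94. The 13 genes of that list had a mean change of -0.03 ± 0.12 (SD, n = 12), with 5 members above 0 and 8 below. EIF4A2, a helicase of translation initiation, had a change of -0.23 ± 0.05. TYW2, a tRNA-modifying enzyme, ARRB1, a beta-arrestin, and the zinc finger gene ZNF835 had changes of 0.15 ± 0.03, 0.15 ± 0.04 and 0.29 ± 0.07. Under placebo CRIPT had a change of -0.17 ± 0.11, below 0 in 4 of 4 pairs, and TYW2 one of 0.10 ± 0.06, above 0 in 4 of 4. RHOBTB2 and ZNF835 had mean changes the other way under placebo, of -0.14 ± 0.09 and -0.25 ± 0.12, each below 0 in 3 of 4 pairs. ARRB1 had one near 0 there, -0.04 ± 0.06, with 2 pairs up and 2 down. In the drug arm 3 further genes of the rule were at low levels. GABRG3, DAB1 and FGF16, at mean levels of 2.93, 3.44 and 3.43, had changes of 0.20 ± 0.05, 0.20 ± 0.05 and 0.21 ± 0.05. The 95% intervals of 97.0% of genes lay within 0.5 of 0. Of the 39 lists 0 passed the exact sign-flip test after adjustment and 1 had an unadjusted p under 0.05. limma's camera with its preset correlation called 8 lists and none with an estimated correlation, where the smallest adjusted p was 0.618.

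**Figure D2:**
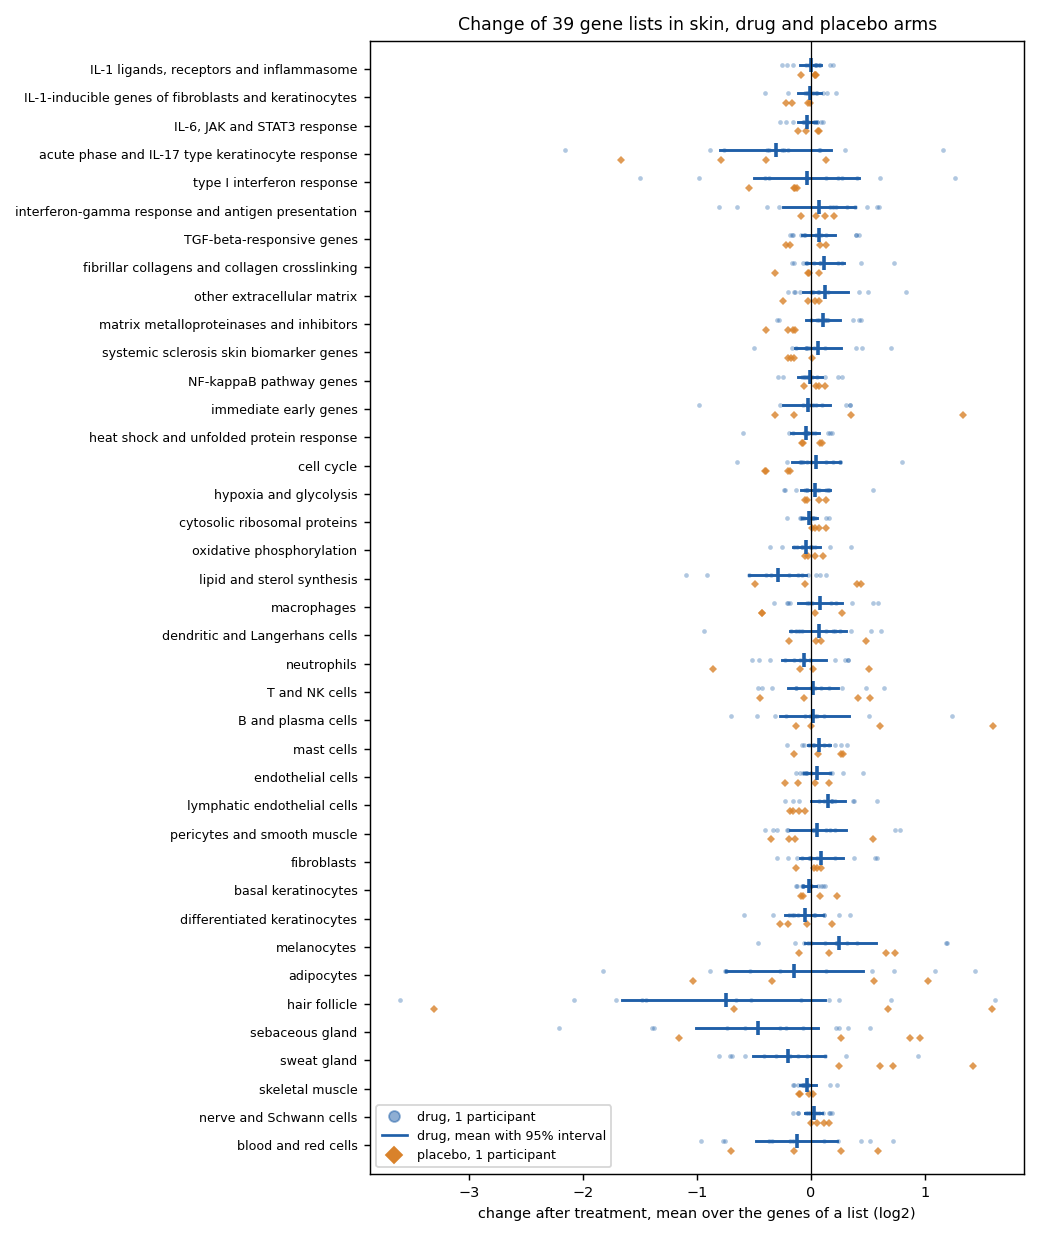
Change after treatment (log2, horizontal axis) of 39 gene lists, each the mean over the genes of the list, with a circle per drug participant, a bar for the drug arm mean and its 95% interval, and a diamond per placebo participant. Only the interval of lipid and sterol synthesis, -0.540 to -0.0482, leaves out 0 in the drug arm, and all 4 placebo diamonds of the sweat gland list lie to the right of 0.

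The second comparison, the randomised one, asked whether the change under the drug differed from that under placebo. Sweat gland genes had the smallest p of the 39 lists. Their mean change was -0.21 ± 0.50 in the drug arm (SD, n = 12) and 0.75 ± 0.49 under placebo (SD, n = 4, above 0 in 4 of 4 pairs), a difference of -0.95 (95% interval -1.57 to -0.348, exact permutation p = 0.00604, adjusted p = 0.236). Of its 9 members, 4 passed when adjusted over the list alone and 0 over all genes. SCGB1D2 and SCGB2A2, secretoglobins of sweat and mammary glands, differed by -2.03 ± 0.64 and -1.84 ± 0.72 (SE), PIP, a secreted glycoprotein of apocrine glands, by -1.55 ± 0.49, and AQP5, the sweat gland water channel, by -0.68 ± 0.24. Without 1 of the 4 placebo pairs the differences of SCGB1D2 and SCGB2A2 were -1.10 ± 0.54 and -0.84 ± 0.61 (SE), with list-alone adjusted p of 0.126 and 0.214. PIP and AQP5 likewise did not pass without 1 placebo pair (list-alone adjusted p = 0.126 and 0.134). SCD passed when adjusted over the sebaceous gland list alone, with a difference of -1.04 ± 0.33 (SE), and not over the lipid and sterol list (adjusted p = 0.0673) or without 1 placebo pair (adjusted p = 0.150). Before treatment SCD was 0.82 ± 0.49 (SE) higher in the drug arm, and after it the drug and placebo arms were at 8.19 and 8.41. Much of its difference in change thus mirrors the gap before treatment.

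Matrix metalloproteinases and their inhibitors had mean changes of 0.11 ± 0.24 in the drug arm (SD, n = 12) and -0.22 ± 0.12 under placebo (SD, n = 4, below 0 in 4 of 4 pairs), a difference of 0.33 (95% interval 0.0579 to 0.584, exact permutation p = 0.0165, adjusted p = 0.321). MMP1, interstitial collagenase, had a change of 0.42 ± 0.26 (SE) with the drug and -1.30 ± 0.45 under placebo, a difference of 1.72 ± 0.52. Before treatment its level in the drug arm differed from that under placebo by -1.08 ± 0.85 (SE), the opposite sign. MMP14, a membrane-bound collagenase, MMP10, a stromelysin, and TIMP1, a metalloproteinase inhibitor, differed by 0.30 ± 0.13, 0.44 ± 0.20 and 0.31 ± 0.16. The lymphatic list differed by 0.27 (exact permutation p = 0.0423, adjusted p = 0.550, n = 12 and 4). Its members CCL21, TFF3 and PDPN, a lymphatic surface glycoprotein, differed by 0.53 ± 0.27 (SE), 0.38 ± 0.22 and 0.28 ± 0.18, and none passed over the list alone. Before treatment the lymphatic list differed between arms by -0.33, and after it the drug and placebo arms were at 5.82 and 5.88. Its difference in change thus mirrors the gap before treatment. The 20 cell cycle genes had mean changes of 0.04 ± 0.34 with the drug (SD, n = 12) and -0.29 ± 0.12 under placebo (SD, n = 4), a difference with an exact permutation p of 0.0879. BUB1B, a spindle checkpoint kinase, differed by 0.51 ± 0.17 (SE), TYMS, thymidylate synthase, by 0.40 ± 0.16, and AURKA and MKI67, mitotic genes, by 0.40 ± 0.17 and 0.36 ± 0.16. No cell cycle gene passed over the list alone (smallest list-alone adjusted p by limma 0.168).

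Among genes of the IL-1 pathway, IL1B had the change of -0.13 ± 0.08 (SE) with the drug and 0.25 ± 0.14 under placebo. The difference was -0.37 ± 0.16, with an adjusted p of 0.957 by limma over all genes and 0.284 over the list alone. Before treatment IL1B was 0.38 ± 0.19 (SE) higher in the drug arm, at 5.37 against 4.99, and after it the arms were at 5.25 and 5.24. The difference in change thus mirrors the gap before treatment and cannot be told apart from it. The IL-1-inducible list differed by 0.09 (95% interval -0.0968 to 0.277, exact permutation p = 0.315, n = 12 and 4). By limma 0 genes passed an adjusted p of 0.05 in the difference and 559 had an unadjusted p under 0.05, 393 higher and 166 lower. The smallest p belonged to LINC01260, a non-coding RNA, with 0.34 ± 0.08 (SE). SYN1, a synaptic vesicle protein, GPR21, an orphan receptor, SLC6A5, a glycine transporter, STK32B, a kinase, and the pseudogene HSD3BP1 differed by 0.41 ± 0.10, 0.42 ± 0.10, 0.41 ± 0.10, 0.46 ± 0.12 and 0.38 ± 0.10. SYN1 and HSD3BP1 had low mean levels of 3.82 and 2.77. PIK3R1, a regulatory subunit of PI3-kinase, and ZNF107 differed by -0.52 ± 0.13 and -0.65 ± 0.17, and ZNF835 and RHOBTB2 by 0.55 ± 0.14 and 0.38 ± 0.10. Of the lists 0 passed the exact permutation test and 3 had an unadjusted p under 0.05, while camera called 12 with its preset correlation and none with an estimated correlation, where the smallest adjusted p was 0.168. The interval of the difference lay within 0.5 of 0 for 79.7% of genes.

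The third comparison was of the biopsies before and after placebo. In 8 of 39 lists all 4 pairs moved one way, against 12.5% of lists by chance, and the smallest exact sign-flip p that 4 pairs allow is 2 in 16 sign patterns. Besides sweat gland genes, the ribosomal protein list (0.06 ± 0.05, SD, n = 4) and the nerve and Schwann cell list (0.08 ± 0.07) were above 0 in all 4. The lists of IL-1-inducible genes (-0.10 ± 0.10), type I interferon response (-0.24 ± 0.20), metalloproteinases, cell cycle and lymphatic endothelium (-0.12 ± 0.06) were below 0 in all 4. Among single genes 0 passed by limma and 395 had an unadjusted p under 0.05, 147 higher and 248 lower. camera called 10 lists with its preset correlation and none with an estimated correlation, where the smallest adjusted p was 0.199. TMPRSS2, an epithelial serine protease, had a change of 0.43 ± 0.11 (SE), AHCYL2 one of 0.28 ± 0.08, and GPR21, SYN1 and ARSJ, a sulfatase, had changes of -0.34 ± 0.09, -0.31 ± 0.08 and -0.31 ± 0.09.

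Before treatment the arms were compared to see how alike randomisation had left them. The 3 lists with the smallest p all had lower levels in the drug arm. Nerve and Schwann cell genes differed by -0.20 (95% interval -0.409 to 0.0156, exact permutation p = 0.0599), endothelial genes by -0.18 (exact permutation p = 0.0670) and lymphatic endothelial genes by -0.33 (exact permutation p = 0.0676), with 12 drug and 4 placebo participants and an adjusted p of 0.879 for each. The interferon-gamma and antigen presentation list was 0.42 higher in the drug arm (exact permutation p = 0.310, n = 12 and 4). IL1B was 0.38 ± 0.19 (SE) higher and IL1RN 0.34 ± 0.16 higher in the drug arm, neither past the test. By limma 0 genes passed and 552 had an unadjusted p under 0.05, 150 higher and 402 lower in the drug arm. The smallest p values were those of DEXI, -0.33 ± 0.07 (SE), FAM184A, -0.42 ± 0.09, ELP5, a subunit of the tRNA-modifying elongator complex, 0.58 ± 0.13, ANGPTL4, an inhibitor of lipoprotein lipase, 0.68 ± 0.15, and MMRN2, an endothelial matrix protein, -0.52 ± 0.12. Of the lists 0 passed the exact permutation test and 0 had an unadjusted p under 0.05. camera called 7 with its preset correlation and none with an estimated correlation, where every adjusted p was 1.

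Levels of many gene lists were kept by a participant from the first biopsy to the second. Of 39 correlations between visits over 16 participants, 24 passed after adjustment by Pearson's r and 20 by Spearman's rho. Mast cell genes gave r = 0.905 (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 0.000195) and rho = 0.874 (permutation p = 3e-05), and r = 0.856 without the 2 participants farthest from the median. IL-1-inducible genes gave r = 0.862 (permutation p = 2e-05, adjusted p = 0.00026), rho = 0.850 (permutation p = 5e-05) and r = 0.812 without those 2, and r = 0.855 in the drug arm alone. T and NK cell genes gave r = 0.879 (permutation p = 6e-05, adjusted p = 0.000468), rho = 0.776 (permutation p = 0.00061) and r = 0.708 without those 2. NF-kappaB genes gave r = 0.780 (permutation p = 0.0033, adjusted p = 0.00715) and rho = 0.512 (permutation p = 0.0448, adjusted p = 0.0698), but r = 0.342 without those 2, on which the relation rests. The lipid synthesis, sebaceous gland and pericyte lists also passed by r (0.597, 0.593 and 0.563) and not by rho. Without the 2 participants farthest from the median their r was 0.367, 0.227 and 0.344. Immediate early genes, transcription factors induced within minutes of a stimulus, gave r = 0.124 (permutation p = 0.565) and rho = 0.232 (permutation p = 0.386), and cell cycle genes gave r = -0.0055 (permutation p = 0.983) and rho = 0.00588 (permutation p = 0.987).

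**Figure D3:**
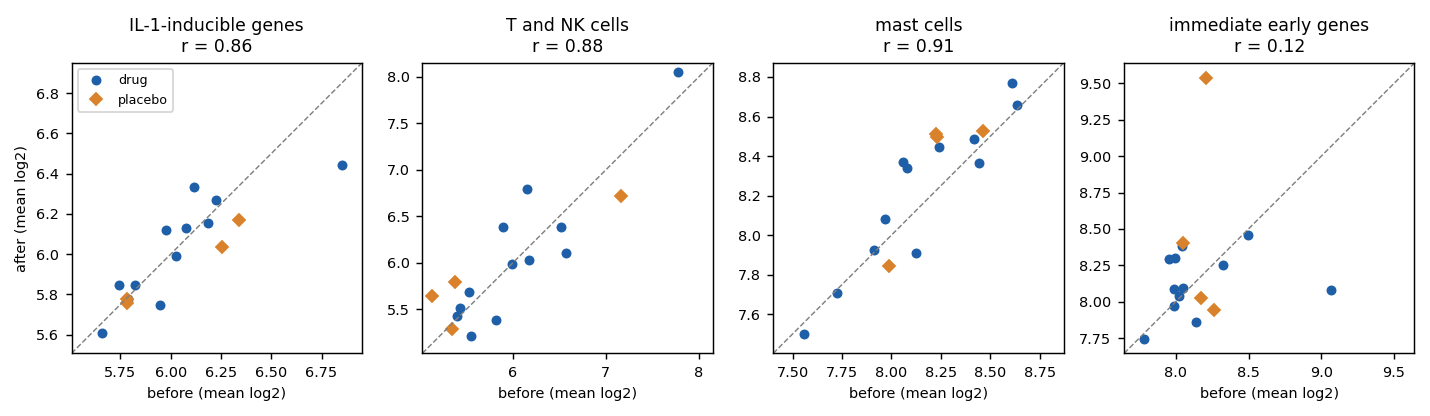
Mean level of a gene list (log2) before treatment on the horizontal axis against the level after treatment on the vertical axis, with a point per participant (circles drug, diamonds placebo) and a dashed line of equal levels. IL-1-inducible, T and NK cell and mast cell genes lie along the line (r = 0.862, 0.879 and 0.905), and immediate early genes do not (r = 0.124).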

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

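The tests of the gene counts and of the sweat gland markers were laid down before their results were seen, and the comparison between arms of the 8 gland genes outside the list was chosen after that of the list itself. 3 gene lists stood out because their changes differed between the arms before adjustment, none of them after it. Sweat gland genes differed by -0.95 (exact permutation p = 0.00604), metalloproteinases and their inhibitors by 0.33 (exact permutation p = 0.0165) and lymphatic endothelial genes by 0.27 (exact permutation p = 0.0423), with 12 drug and 4 placebo pairs.

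In the placebo arm a value lay far from the others in 3 of 56 groups of 4 values examined, where chance gives about 2.8. The distant change was -0.0908 for the list of IL-1 ligands, receptors and inflammasome, -0.55 for the type I interferon response and 1.51 for CCL18.

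A candidate explanation of the sweat gland difference is the amount of gland that each biopsy caught. The change of the list followed that of 8 gland genes outside it, with r = 0.905 over 16 participants (permutation p = 1e-05, the smallest that 100000 permutations can give), rho = 0.932 (permutation p = 2e-05) and r = 0.892 without the 2 participants farthest from the median. These 8 genes had mean changes of -0.03 ± 0.29 with the drug (SD, n = 12) and 0.37 ± 0.08 under placebo (SD, n = 4, exact permutation p = 0.0192). A coordinated change of expression inside gland cells would give the same relation, so an effect of treatment on the gland stays open and untested.

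Chance cannot be excluded for the numbers of genes at an unadjusted p under 0.05. With visits swapped at random within pairs, 33 of 100 splits gave as many genes as the 694 of the drug arm, and the highest other split gave 1439. With arm labels drawn at random, 54 of 100 gave as many as the 559 of the difference (highest other 1446) and 43 of 100 as many as the 552 before treatment (highest other 1823). The 4 placebo pairs allow 8 splits, too few for a share under 0.05, and 5 of them gave at least the real 395, with 660 in the highest other.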

How the results depend on the processing

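The appendage covariates and the use of entries without a gene symbol were chosen after seeing the data, as were the refits of genes passing over a list alone, and the other alternatives before. By limma 0 genes passed in each comparison under every alternative run but 1, with unadjusted counts of 694 (drug), 395 (placebo), 559 (difference) and 552 (before treatment) in the fit as reported. With hair follicle, sebaceous and sweat gland list levels as covariates, 2 genes differed between arms, RGS1 by -1.64 ± 0.25 (SE, adjusted p = 0.0450) and TNFSF14 by -0.82 ± 0.10 (adjusted p = 0.0116), named after their values were seen, against -0.64 ± 0.35 and -0.18 ± 0.19 (adjusted p = 0.957 for both) without them. The cause was not tested. Without the participant block the counts of genes passing were 0 as well, so the pairing changed no call. Lists passing went from 0 to 8 (drug), 12 (difference) and 7 (before treatment) with camera's preset correlation, which takes genes of a list as nearly independent, and it called 10 in the placebo arm. With an estimated correlation camera called 0 in all 4. Leaving out 1 pair in turn gave 0 genes and 0 lists throughout, with unadjusted counts of 485 to 840 (drug), 239 to 522 (placebo), 279 to 790 (difference) and 277 to 890 (before treatment), while the placebo lists moving one way ranged from 9 to 14, since 3 pairs go one way more often by construction. For 94 results of named genes and lists, 401 alternative values gave 0 that passed. A turn of sign by more than the SE (genes) or the SD between participants (lists) occurred in 0, and smaller turns were not counted. The 401 values covered centred arrays and the lowest and highest leave-one-out values, the fit without the block for genes, and the median, the filter on dim genes and the second code for lists, not camera or the covariates. For genes they left out the second code, without which the drug arm means of IL1A, CCL18 and THBS1, among others, turned sign. Genes that passed over a list alone were refitted without each pair. In the drug arm NEB, and SCD in the sebaceous list, passed in 16 of 16 fits, SCD and ELOVL6 in the lipid list in 12, CCL21 in 10 and TFF3 in 9. In the difference SCGB1D2, PIP and SCD passed in 14, AQP5 in 12 and SCGB2A2 in 8. Without the 2 drug pairs that carry a second code the extracellular matrix list mean was 0.02 in place of 0.12. Using all probe sets of a gene, or their mean, was not run because the table has 1 entry per gene, and lists left with fewer than 4 genes by the filter on dim genes gave no value.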

Other observations

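The comparison of pairs by the second code was chosen after its result was seen, and the other tests before. PMEL and TYRP1, outside the naming rule, were named after their values were seen. Melanocyte genes, which had no place in the comparisons above, had mean changes of 0.25 ± 0.50 in the drug arm (SD, n = 12, exact sign-flip p = 0.121) and 0.36 ± 0.40 under placebo (SD, n = 4). PMEL, a scaffold protein of pigment granules, had a change of 0.40 ± 0.17 (SE) with the drug and 0.46 ± 0.30 under placebo, and TYRP1, an enzyme of melanin synthesis, 0.36 ± 0.19 and 0.50 ± 0.32. Adipocyte genes had mean changes of -0.15 ± 0.95 with the drug (SD, n = 12) and 0.05 ± 0.92 under placebo (SD, n = 4), and B and plasma cell genes of 0.01 ± 0.49 and 0.52 ± 0.79.

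In the 2 drug pairs whose first array carried a second code in its title, matrix, fibroblast and macrophage genes had larger changes than in the other 10 pairs. The list means were 0.58 against 0.02 for fibrillar collagens, 0.41 against -0.003 for TGF-beta-responsive genes, 0.57 against -0.02 for macrophages and 0.57 against -0.04 for the skin biomarker genes. In these 4 lists both pairs lay above all 10 others (exact permutation p = 0.0152 each, the smallest that 66 splits can give, adjusted p = 0.148 over 39 lists). For the other extracellular matrix list the difference was 0.61 and for fibroblasts 0.47 (exact permutation p = 0.0303 and adjusted p = 0.197 each, 2 against 10 pairs). COMP had mean changes of 1.31 and 0.12 in the 2 sets of pairs. Before treatment these 2 pairs had lower levels, by -0.45 for fibrillar collagens (exact permutation p = 0.121), -0.52 for the biomarker genes and -0.47 for macrophages (exact permutation p = 0.212 each), -0.44 for the other extracellular matrix list (exact permutation p = 0.106) and -0.40 for fibroblasts (exact permutation p = 0.0455, not adjusted). Something that the second code marks, such as another study or another time between biopsies, may lie behind this, but with 2 pairs it cannot be told apart from chance, and the labels do not say what the code means.

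A candidate explanation of the lower lipid synthesis values in the drug arm is less sebaceous gland in the second biopsy. The change of the lipid list without SCD followed that of 6 sebocyte genes outside it, with r = 0.964 over 16 participants (permutation p = 1e-05, the smallest that 100000 permutations can give), rho = 0.950 (permutation p = 1e-05) and r = 0.953 without the 2 participants farthest from the median. The drug arm mean of the list without SCD was -0.26 ± 0.40 (SD, n = 12, exact sign-flip p = 0.0312) before and -0.0903 ± 0.103 (SD, n = 12, exact sign-flip p = 0.0117) after regression on those genes. FAR2 and FADS2, enzymes of sebaceous lipid synthesis, are among those 6 genes. A coordinated change of lipid gene expression inside gland cells would give the same relation, so the regression cannot separate gland content from expression. Whether a smaller change beyond gland content remains stays open. The value left was not set against placebo, and neither value is adjusted over the 39 lists.

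A participant's own level, kept over both visits, might also come from processing both arrays together. Lists of ribosomal proteins and oxidative phosphorylation, chosen as housekeeping controls, had a mean r between visits of 0.553, with r = 0.623 and 0.482, and r = 0.401 and 0.368 without the 2 participants farthest from the median. The mean thus rests partly on those participants, and shared processing is neither excluded nor shown, and the labels give no processing batch. IL-1-inducible, T and NK cell and mast cell genes had larger r (0.862, 0.879 and 0.905), a difference that was not tested.

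Participants with higher IL-1-inducible expression may respond more to an IL-1 inhibitor. In the drug arm the change of the list against the mean of both visits gave r = -0.335 (permutation p = 0.279, n = 12) and rho = 0.0979 (permutation p = 0.766), and r = 0.398 without the 2 participants farthest from the median. The sign thus rests on those 2 participants, and the relation was not detectable in 12 pairs.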
